A study of Triticum urartu with 119 samples.

How the data were processed

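DAP-seq measures where a tagged transcription factor made in vitro binds fragmented, naked genomic DNA, so chromatin does not enter the measurement, while DNA methylation of the leaves it came from can. Per the labels' protocols, genomic DNA from leaves of Triticum urartu seedlings (accession G1812) was fragmented and given sequencing adapters, each full-length factor was expressed with a Halo tag in wheat germ extract and bound to beads, and the eluted DNA was amplified with indexed primers. The empty tag vector was run in the same way to capture background DNA.

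The peak lists were made by the authors with MACS2 2.2.6, per the file headers, 1 list per library and without pooling of libraries. Per the file headers, paired-end alignments whose names carry a quality filter and removal of duplicates were compared with the merged Halo background of 3721706 fragments, with a genome size of 4821609433 bp, a q-value threshold of 0.05, the larger dataset scaled down to the smaller, and the local background estimate switched off in all 116 lists. fastp 0.20.0 and Trim Galore 0.4.4 are named in the submitters' processing notes. The name of the input folder of 15 lists contains that of the aligner bwa; its version, the aligner of the other lists and the genome build are not given in the sources used here. Each list gives, per the file headers, the position, length and summit of each peak, the pileup signal at the summit, the −log10 of its p-value and q-value, and its fold enrichment over the expected pileup. All these values are the authors' own and are used here only to rank, filter and describe peaks within a list. The fold of a peak was checked against its pileup: in each list the ratio of (pileup + 1) to fold was constant, with a spread of at most 0.198%. The Halo background therefore set 1 expected value per library and removed no background that differs from place to place.

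Libraries were grouped by the family in their label. Libraries of a family are of different factors, so they replicate the family and not a factor, and p-values measure the spread between such libraries, which may in part be technical. The Halo samples entered no test. The depth of a library was taken as the total fragments in its list's header. The input folder in the header separated 101 from 15 libraries and was treated as a possible batch. The samples are also listed in a run before the Halo samples and a further run after them. What this order stands for is not given, and it entered no test. Each list's most enriched peaks were taken by −log10 q, then fold, then position. Since a single expected value was used per list, ranking by fold gives the same order.

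A peak was represented by a 201 bp window centred on its summit. The overlap of 2 lists was the share of the windows of one that overlap a window of the other by at least 1 bp, averaged over both directions, with the 1000 strongest peaks of the 89 lists that held as many. The 27 shorter lists entered the counts of peaks, the values given for them and the alternatives with the 500 or 100 strongest peaks (113 and 116 lists). Regions were formed by chaining overlapping windows, which lets a region grow beyond 201 bp. The length of a sequence was taken as the largest peak end in any list. Exact 95% intervals (Clopper-Pearson) are given for shares in 1 list. Fragments amplified by PCR are not independent molecules, and these intervals cover counting error only.

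Family differences in log10 peak number and in distal share were tested by the between-family share of the variance, and overlaps by the mean of same-family pairs minus that of the other pairs, with family labels shuffled 100000 times over libraries (two-sided permutation tests, smallest p 1e-05). For each family with 3 or more included libraries the overlap within it was set against that with other families, with Benjamini-Hochberg adjustment. Links between families were tested in the same way on the 5000 strongest peaks, for families with 2 or more lists, by shuffling the labels of the lists outside each family; the larger of both p-values was kept. Recurrent regions, held by at least 10 libraries, were tested against 100 circular shifts. Correlations are given with permutation p-values. Tests with under 10 values in a group used the same shuffles of labels over all libraries.

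The overlap and recurrent-region steps alone were run on simulated lists: 48 libraries of 6 families with 1000 windows each, sharing 30% within a family. The overlap came out at 31.0% within and 1.02% between families, all 6 families passed, all 40 planted recurrent regions were found with 0 in the shifts, and 5% of 200 shuffled labelings fell under 0.05. A test by shuffled labels gives that last share by construction. The real lists overlapped by 14.7% between families and gave 88.7 regions in the mean shift. The simulation does not cover such a common background.

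The tests of peak number, of same-family overlap and of recurrent regions, with their alternatives, were chosen before the data were examined. The alternatives were other numbers of strongest peaks, other thresholds, other definitions of overlap, pooled subfamilies, and libraries or regions left out. The distal share, the links between families, the correlations and the family-typical regions were chosen afterwards. The rule for named libraries, fixed beforehand, was the 3 highest and 3 lowest of each measure and each library closest to another family. The rule for named genes (the genes with promoters in the most lists, and the 3 most typical of each family) was carried over to regions, since no annotation of the files' build was used. For the same reason the planned searches for known motifs, promoters, repeats and groups of stress genes were not run, and no statement about genes or transposable elements is made. The gene table at hand is of assembly Tu2.1, whose relation to the files' coordinates is not stated, and its positions were not used. All steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.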

Results

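The data were in vitro binding profiles of transcription factors on the naked genome of Triticum urartu, a wild diploid wheat of the A genome lineage. The assay was DNA affinity purification sequencing (DAP-seq): each factor was made in a cell-free wheat germ extract with a Halo tag and fixed on beads. It was then mixed with fragmented genomic DNA from seedling leaves of 1 accession, and the fragments it kept were sequenced. The stated aim of the series was to chart the circuits through which factors act in abiotic stress, and its title asks how transposable elements of the lineage changed them. There were 119 samples: 116 libraries, each of a different factor, and 3 samples with the Halo tag alone, which served as the common background and had no peak list of their own here. The 116 factors fell into 23 families by their labels, of which MYB (24 libraries), NAC (19), WRKY (14), bZIP (11), bHLH (9) and AP2-DREB (7) were the largest. No factor had a second library, so the spread given below is that between factors of a family, which includes both technical variation and real differences between proteins.

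The lists held 3705802 peaks in all, and merged peaks covered 922 Mb, or 19.1% of the genome size that the peak caller was given. A single list held between 250 peaks (B3-10) and 252067 (ZFHD2), with a median of 2426. Libraries had 0.706 M to 37.0 M fragments (median 4.24 M fragments). The merged Halo background had 3.72 M fragments, and 62 libraries were deeper than that background. For 8 libraries the list's header names another member of the same family than the label does: AP2-DREB-1 (header AP2-DREB-18), AP2-DREB-18 (AP2-DREB-19), AP2-DREB-19 (AP2-DREB-1), bZIP2 (bZIP20), bZIP20 (bZIP2), NAC2 (NAC26), NAC26 (NAC29) and NAC29 (NAC2). They are named by their labels below, and which member each holds stays open, while their family does not.

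The first comparison asked whether families differ in the number of peaks listed for their members. WRKY factors, a plant family known for roles in defence and stress, had the longest lists of the larger families: a median of 69679 peaks (range 1610 to 160428, n = 14) and 4.57 ± 0.667 on the log10 scale (SD). AP2-DREB factors, named for binding the dehydration-responsive element, had a median of 17594 (5359 to 221871, n = 7). NAC and bZIP libraries had medians of 2662 and 2690, bHLH 1902, MYB 1842 and C2C2 666. The highest lists of all were ZFHD2 (252067), AP2-DREB-19 (221871) and NAC15 (181336), and the lowest were B3-10 (250), bZIP1 (251) and bZIP5 (311), which were also the 3 shallowest libraries.

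Family accounted for 30.3% of the variance of log10 peak number over the 11 families with 3 or more libraries, which leaves out 15 libraries of 12 families (two-sided permutation test, 100000 shuffles, p = 0.00019), and for 29.6% (p = 0.00023) within the 86 libraries whose inputs came from 1 folder by the list headers. Of the 11 families, WRKY alone differed from the rest after adjustment. Its geometric mean was 9.60-fold that of the other libraries (permutation p = 1e-05, the smallest that 100000 shuffles can give, Benjamini-Hochberg adjusted p = 0.00011). AP2-DREB stood 5.10-fold above the rest and C2C2 at 0.144-fold, and neither passed (permutation p = 0.0297 and 0.0237, adjusted p = 0.109 for both). After removal of the linear trend of peak number on fragments, an alternative chosen after the data were seen, WRKY stood 4.27-fold above the rest (permutation p = 0.0016, adjusted p = 0.0176). In the run of samples before the Halo samples, lists other than NAC26 (1198 peaks) held at least 3043 (NAC17). In the run after them, lists other than MYB14, NAC1 and NAC12 held at most 2690 (bZIP8). All AP2-DREB libraries and all WRKY libraries but WRKY14 are in the first run, and all C2C2 libraries in the second. The family differences in peak number were not separated from this order.

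**Figure D1:**
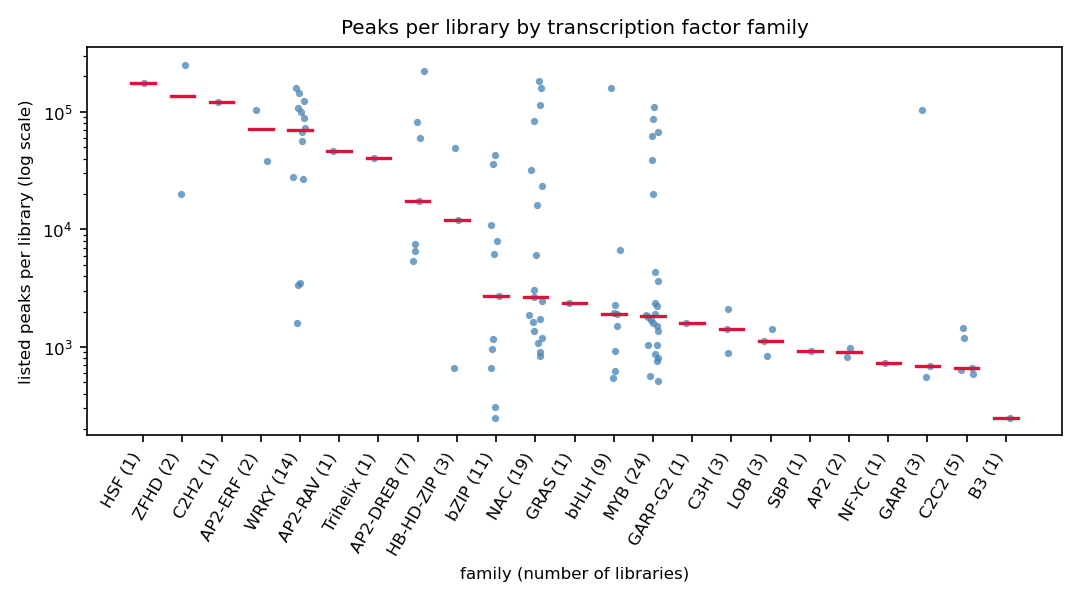
Listed peaks per library (log scale, vertical axis) for the 23 families (horizontal axis, number of libraries in brackets). Each point is 1 library and each bar the family median, which was 69679 for WRKY and 1842 for MYB.

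Depth and peak number rose together. Over all 116 libraries Pearson's r between log10 fragments and log10 peaks was 0.570 and Spearman's rho 0.598 (both permutation p = 1e-05, the smallest possible, adjusted p = 4.5e-05 over the 9 relations computed). Without the 2 libraries farthest in depth r was 0.605. Within the larger input folder (all but 15 libraries) r was 0.515 and rho 0.575 (both permutation p = 1e-05, adjusted p = 4.5e-05). Within the other folder (n = 15) r was 0.897 (permutation p = 0.00058, adjusted p = 0.00130) and rho 0.507 (p = 0.056, adjusted p = 0.084), and r was 0.513 without the 2 farthest. The relation was tight in bZIP (rho 0.936, r 0.927, permutation p = 8e-05 and 6e-05, adjusted p = 0.00024 and 0.00018) and was not detected in NAC (rho -0.0561, r 0.0767, p = 0.821 and 0.754, both also after adjustment). By rho it did not pass in WRKY (0.305), bHLH (0.467), MYB (0.459) or AP2-DREB (0.786), with permutation adjusted p = 0.326, 0.274, 0.0551 and 0.084. By r, MYB (0.428) and AP2-DREB (0.784) passed, at permutation adjusted p = 0.0495 and 0.0475. For AP2-DREB r was 0.289 without the 2 farthest. Differences between the families were not tested. Depth did not fix the length of a list: MYB12, the deepest library, had one of the shorter lists (1495 peaks) from 37.0 M fragments. WRKY12 had 72310 peaks from 1.49 M fragments.

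The second comparison asked whether factors of 1 family bind the same sites. They did so more often than factors of different families. Among the 89 lists with at least 1000 peaks, the 1000 strongest peaks of 2 factors of a family overlapped by 22.3% on average and those of 2 families by 14.7%, a difference of 7.62 points (461 same-family pairs of 3916, permutation p = 1e-05, the smallest possible). With the 5000 strongest peaks of the 50 lists that had as many, the values were 27.2% and 3.28%, an 8.27-fold ratio (permutation p = 1e-05). Within the larger input folder the differences were 8.51 points (79 libraries) and 24.4 points (48 libraries), each at permutation p = 1e-05, the smallest possible. With only the 100 strongest peaks of each list the difference was 3.15 points and did not pass (permutation p = 0.181).

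WRKY and AP2-DREB passed the test family by family at 1000 peaks, of 6 families tested. WRKY libraries shared 34.3% of their peaks with each other and 11.3% with other families (n = 14, permutation p = 1e-05, the smallest possible, adjusted p = 6e-05), and AP2-DREB libraries 22.7% and 9.32% (n = 7, permutation p = 0.00179, adjusted p = 0.00537). The AP2-DREB call ended without its 3 libraries whose header names another member (n = 4, permutation p = 0.0474, adjusted p = 0.0791). It also ended with the 500 strongest peaks (n = 7, permutation p = 0.116, adjusted p = 0.213 over 11 families). NAC (19.4% against 15.4%), bHLH (25.1% against 17.7%), bZIP (20.2% against 15.9%) and MYB (17.5% against 15.4%) did not pass, with permutation p = 0.0353, 0.0392, 0.125 and 0.237 and adjusted p = 0.0588, 0.0588, 0.15 and 0.237. At 5000 peaks all 5 families that could be tested passed. WRKY lists shared 40.5% within and 3.02% outside (n = 11, permutation p = 1e-05, adjusted p = 5e-05) and AP2-DREB lists 27.6% and 3.22% (n = 7, permutation p = 0.00012, adjusted p = 0.0003). MYB lists shared 15.1% and 3.80% (n = 6, permutation p = 0.00933, adjusted p = 0.0151), NAC 10.1% and 2.56% (n = 8, p = 0.0121, adjusted p = 0.0151) and bZIP 11.9% and 4.15% (n = 5, p = 0.0394, adjusted p = 0.0394). The bZIP call ended when bZIP17 or bZIP7 was left out (permutation adjusted p = 0.0507 and 0.0654). The MYB mean rests on MYB13, MYB26 and MYB27, whose pairs shared 44.9%, 42.3% and 71.0%, while all other MYB pairs shared at most 13.9%. The MYB test was not repeated with lists left out.

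Within WRKY the most similar lists were WRKY20 and WRKY21, which shared 77.5% of their 5000 strongest peaks (exact 95% interval 76.3% to 78.7%, counting error only), and WRKY15 and WRKY16, which shared 69.6%. WRKY12 had the highest mean overlap with its family, 49.4% over the 10 other WRKY lists. By its 5000 strongest peaks WRKY8 stood apart, with a mean of 11.7% with the other WRKY lists and 2.55% with other families. In AP2-DREB all 21 pairs of lists shared between 9.98% and 60.3%. The MYB, NAC and bHLH families held pairs of close lists beside members with little in common. MYB26 and MYB27 shared 71.0% of their 5000 strongest peaks (69.8% to 72.3%), NAC14 and NAC15 57.5% (56.1% to 58.9%), and bHLH10 and bHLH11 48.8% (47.4% to 50.2%). MYB19, NAC1 and NAC12 had mean overlaps with their own families of 2.28%, 1.45% and 3.15%, against 2.24%, 1.71% and 4.03% with other families. The lowest means at 1000 peaks were those of NAC2 (3.53%), MYB17 (6.61%) and NAC18 (6.61%), and the highest were those of the AP2-ERF-13 and AP2-ERF-23 pair (56.0%) and of WRKY15 (44.6%).

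The AP2 superfamily gave the one link between families that passed a test. AP2-DREB and AP2-ERF factors, the latter named for the response to ethylene, shared 11.9% ± 5.28 (SD over 14 pairs of libraries) of their 5000 strongest peaks, while AP2-DREB lists shared 2.80% and AP2-ERF lists 2.08% with the remaining lists (permutation p = 0.00125, the larger of the tests from each side, adjusted p = 0.045 over 36 pairs of families). AP2-DREB-8 overlapped AP2-ERF-13 by 21.2% (20.1% to 22.3%) and AP2-ERF-23 by 20.9%, while AP2-ERF-13 and AP2-ERF-23 shared 67.8% with each other. Without either AP2-ERF list the overlap was 11.1% and 12.7% (permutation p = 0.0238 for both, the smallest possible with 1 AP2-ERF list among 42), which alone would not pass an adjustment over 36 pairs. At 1000 peaks the overlap of the families was 9.52% and did not stand out from the rest (permutation p = 0.934). None of the other 35 pairs of families passed: ZFHD with bZIP came next at 7.22% (permutation p = 0.0314, adjusted p = 0.377), then MYB with ZFHD at 6.94% (p = 0.0149, adjusted p = 0.268).

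**Figure D2:**
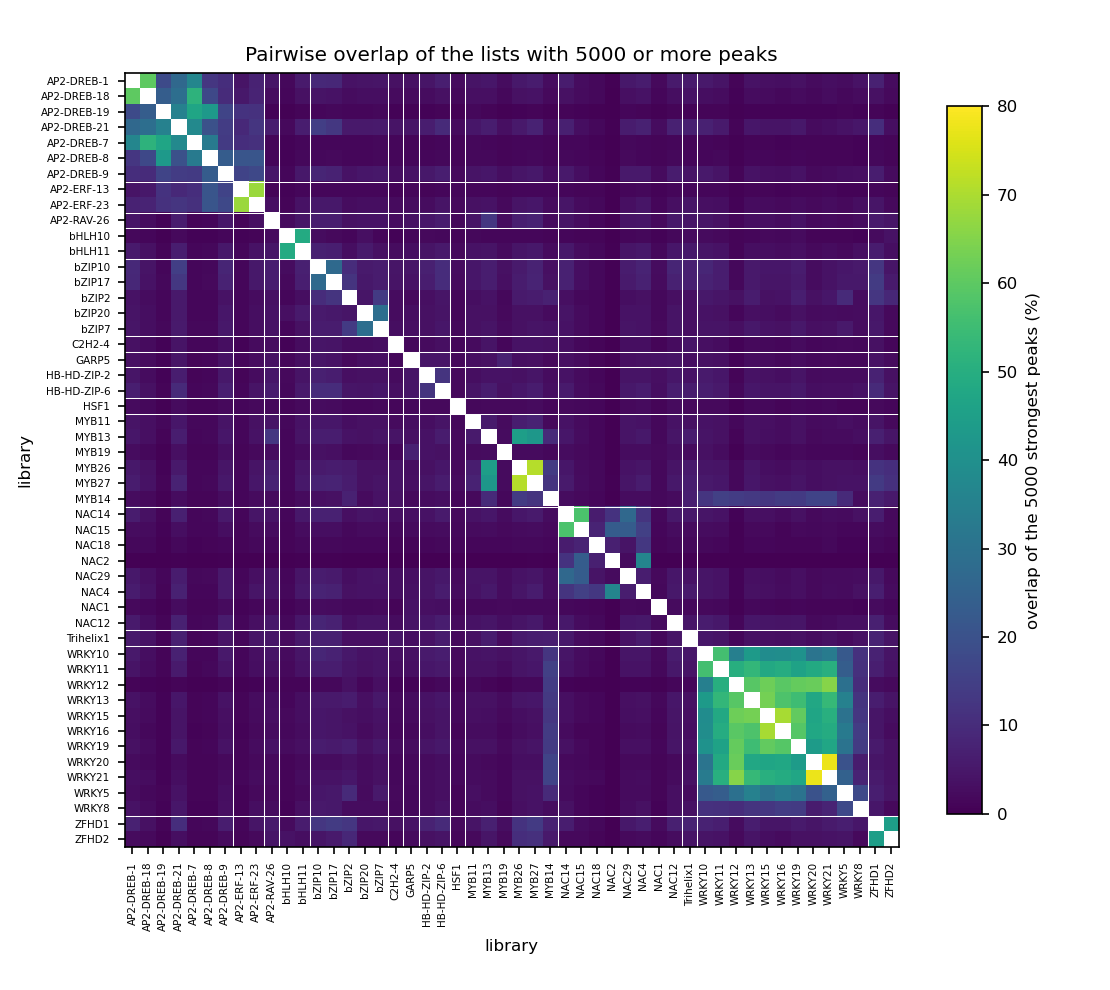
Overlap of the 5000 strongest peaks (percent, colour) for each pair of the 50 lists with at least 5000 peaks, ordered by family along both axes, with thin lines between families and the diagonal left blank. The WRKY block averages 40.5% and AP2-DREB with AP2-ERF 11.9%, against 3.28% over all pairs of different families.

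At 5000 peaks, 41 of the 45 lists that had a family member among the 50 were closest to a list of their own family. The 4 others were MYB14, closest to WRKY21 (16.0%, with 13.9% for its closest MYB list), MYB19, closest to GARP5 (7.28%), NAC1, closest to GARP5 (4.06%), and NAC12, closest to bZIP10 (8.18%). With the 1000 strongest peaks NAC12 was closest to NAC9 (48.2%), whose list is too short for the set of 50. Of the 5 lists with no family member, AP2-RAV-26 was closest to MYB13 (12.5%), GARP5 to MYB19 (7.28%), Trihelix1 to ZFHD1 (7.60%), C2H2-4 to bZIP10 (4.52%) and HSF1, the heat shock factor, to bZIP10 (2.60%).

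At 1000 peaks 50 of 82 such lists were closest to their own family. The 32 others, which include MYB19 although it was tied at 13.8% with GARP5, NAC8 and its own family's MYB12, were C2C2-4, C2C2-5, LOB2, LOB5, C3H-1, HB-HD-ZIP-6, AP2-DREB-9, AP2-DREB-21, WRKY30, bHLH5, bHLH7, bHLH16, bZIP8, bZIP11, NAC1, NAC23, NAC26, NAC27 and the MYB lists 6, 11, 12, 14, 16, 17, 18, 19, 20, 22, 23, 31, 32 and 34. Most of them were closest to a list that is itself short: NAC23 (2481 peaks) and bHLH5 (2270 peaks) shared 53.8% of their 1000 strongest peaks, and so did NAC23 and MYB23 (2238 peaks). The regions behind this sharing are described next.

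The third comparison asked which regions recur over the lists. The 89000 strongest peaks of the 89 lists fell into 39682 regions, of which 29176 (73.5%) were in 1 list only and 10506 in more than 1; of the latter, 6467 (61.6%) were held within 1 family. A small set recurred widely: 1168 regions were held by at least 10 libraries, while circular shifts of each list along its own sequences gave 88.7 on average and at most 104 in 100 shifts (one-sided p = 0.0099, the smallest that 100 shifts can give). On the 7 chromosomes alone, an alternative chosen after the data were seen, the count was 1008 and no shift gave any, so the regions found in shifts lay on short contigs. Of the 1168 regions, 975 were held by 5 or more families, 128 by 2 to 4 families and 65 by 1 family, which was WRKY in every case. Only MYB (19 lists), NAC (17) and WRKY (14) had the 10 lists that such a region takes. The recurrent regions lay on contigs outside the 7 chromosomes in 13.7% of cases, against 4.92% of all regions.

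The most widely held region was on chromosome 5 from 619147301 to 619147526, in 88 of the 89 lists and all 19 families. Next were a region on contig TuUngrouped_contig_325 from 50248 to 50671 (88 lists), regions on chromosome 3 from 44169053 to 44169304 and on chromosome 4 from 50017591 to 50017803 (87 lists each), and regions on chromosome 1 from 14874416 to 14875015 and on chromosome 3 from 297941168 to 297941720 (86 lists each). The 20 most widely held regions were in 81 to 88 lists, and all 6 regions named here also had a summit in each of the 27 lists with under 1000 peaks. The genome build of these positions is not given in the sources used here, and genes at them were not analysed.

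The regions held by 5 or more families numbered 1195 and took between 1.6% (NAC2) and 75.4% (NAC23) of a list's 1000 strongest peaks, with a median of 34.8%. The lowest shares after NAC2 were those of WRKY20 (3.2%) and WRKY12 (5.2%), and the highest after NAC23 were those of bHLH5 (75.3%) and C3H-1 (74.3%). The share fell with the length of the list: Pearson's r with log10 peak number was -0.807 and Spearman's rho -0.749 (n = 89, both permutation p = 1e-05, the smallest possible, adjusted p = 1.25e-05 over 5 relations), and r was -0.803 without the 2 lists farthest in length. Within the larger input folder r was -0.804 and rho -0.739 (n = 79, both permutation p = 1e-05, adjusted p = 1.25e-05). Within the other folder (n = 10) r was -0.895 (permutation p = 0.0111, adjusted p = 0.0111) and rho -0.370 (p = 0.294, adjusted p = 0.294). There r was 0.0558 without the 2 farthest lists, so the relation in that folder rests on those 2. At 5000 peaks rho was -0.653 (n = 50, permutation p = 1e-05, adjusted p = 1.25e-05). In the 27 lists with under 1000 peaks, between 38.9% (bZIP4) and 81.2% (GARP2) of all peaks lay in these regions, with a median of 66.0%.

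**Figure D3:**
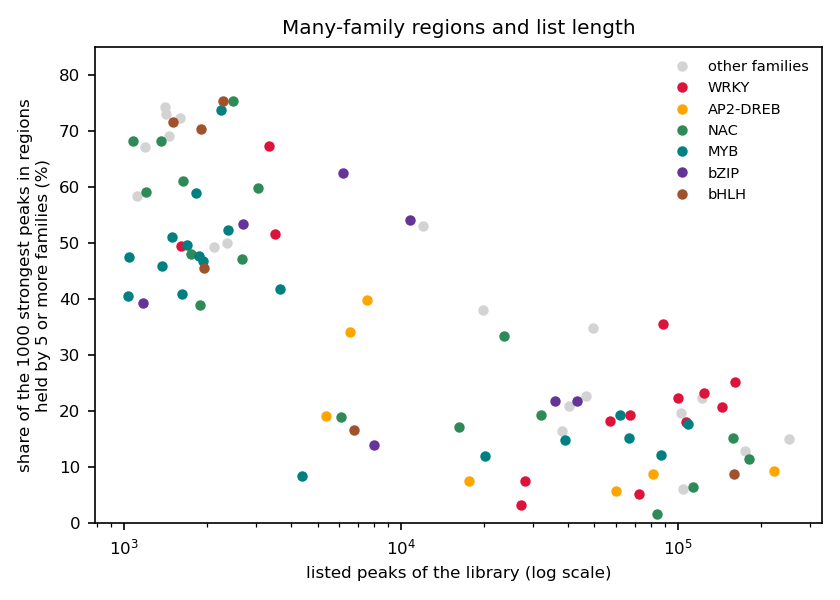
Share of the 1000 strongest peaks that lie in regions held by 5 or more families (percent, vertical axis) against the number of listed peaks (log scale, horizontal axis) for the 89 lists with at least 1000 peaks, coloured by family. The share runs from 75.4% in NAC23 (2481 peaks) to 1.6% in NAC2 (84120 peaks).

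Beside this common set, some regions were held by 1 family only among the 5000 strongest peaks of the 50 lists with as many. Weaker peaks of the other lists were not counted, so such a region can still be listed for another family. Among the 5000 strongest peaks, 3092 regions were held by at least 50% of the 11 WRKY lists, and 1946 of them (62.9%) by no list of another family. The same counts were 2121 and 1489 for the 7 AP2-DREB lists, 2303 and 1505 for the 6 MYB lists, 624 and 376 for the 8 NAC lists and 687 and 128 for the 5 bZIP lists; 50% means 3 lists in MYB and bZIP and 4 in AP2-DREB and NAC, so the counts are not on 1 scale. With the 1000 strongest peaks of all 89 lists, which also changes the lists and with them the 50% limit, 258 of 624 such regions in WRKY and 182 of 294 in AP2-DREB were in no list of another family, but 0 of 239 in MYB, 0 of 266 in NAC, 2 of 293 in bZIP and 7 of 575 in bHLH. At 5000 peaks the close lists MYB13, MYB26 and MYB27 can meet the MYB limit of 3 lists alone. They held 1788, 2866 and 2692 peaks shared within MYB only, against 188 in MYB11 and 435 in MYB14.

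The regions most typical of a family, by the difference in the share of its own and of other lists at 1000 peaks, were sharpest in WRKY and AP2-DREB. A region on chromosome 1 from 50263934 to 50264227 was in 14 of 14 WRKY lists and 1 of the 75 others, as were regions on chromosome 2 from 682629824 to 682630126 and on chromosome 3 from 683878576 to 683878865. A region on chromosome 5 from 577592421 to 577592660 was in 7 of 7 AP2-DREB lists and 0 of 82 others, and regions on chromosome 3 from 741590280 to 741590524 and on chromosome 5 from 321390965 to 321391327 were in 7 of 7 and 2 of 82. In NAC, a region on chromosome 3 from 539205618 to 539205941 was in 10 of 17 lists and 7 of 72 others, and one on chromosome 4 from 339483168 to 339483377 was in 8 of 17 lists and 0 of 72 others. In bHLH, a region on chromosome 3 from 662331542 to 662331792 was in 5 of 6 lists and 12 of 83 others, and one on chromosome 5 from 6206792 to 6207040 was in 4 of 6 lists and 0 of 83 others. In bZIP, a region on chromosome 6 from 253012440 to 253013047 was in 6 of 7 lists and 8 of 82 others, and in MYB one on contig TuUngrouped_contig_7201 from 7132 to 7579 was in 9 of 19 lists and 8 of 70 others. The third region of NAC was in 12 of 17 lists and 17 of 72 others, and that of bHLH in 6 of 6 and 33 of 83. The remaining bZIP regions were in 7 of 7 lists and 22 of 82 others, and in 5 of 7 and 11 of 82. Those of MYB were in 8 of 19 lists and 6 of 70 others, and in 9 of 19 and 10 of 70.

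The place of the strongest peaks along the chromosomes, a comparison added after the data were seen, also differed between families. Peaks were concentrated towards the chromosome ends, where wheat chromosomes are known to be rich in genes: in 88 of 89 lists the share of the 1000 strongest peaks in the outermost 20% of the chromosomes had an exact 95% interval above 20%, the exception being NAC2 at 18.5% (16.1% to 21.1%). The 20% is that of an even spread of peaks. How evenly reads can be aligned, and how the Halo background lies along the chromosomes, was not examined. An excess over 20% therefore need not reflect binding by the factors, and its relation to genes was not tested. Family accounted for 54.4% of the variance of this distal share over 70 libraries of 6 families (permutation p = 1e-05, the smallest possible), and for 54.8% within the larger input folder (64 libraries, permutation p = 1e-05). WRKY lists had 54.8% ± 11.2 (SD, n = 14) of their strongest peaks there, against 38.2% in the other 5 families (permutation p = 1e-05, adjusted p = 6e-05 over 6 families). NAC lists had 34.2% ± 6.91 (n = 17), against 43.9% in the other 5 families (permutation p = 0.00041, adjusted p = 0.00123). That 43.9% includes the WRKY lists, and NAC was not tested without them. AP2-DREB (47.1% ± 3.91, n = 7), MYB (37.4% ± 5.22, n = 19), bHLH (40.9% ± 3.57, n = 6) and bZIP (38.8% ± 6.83, n = 7) did not pass (permutation p = 0.126, 0.041, 0.885 and 0.459, adjusted p = 0.189, 0.082, 0.885 and 0.551).

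The highest distal shares were those of WRKY20 (69.5%, interval 66.4% to 72.4%), WRKY21 (67.2%) and WRKY11 (65.0%), and the lowest those of NAC2 (18.5%), NAC4 (25.0%) and NAC18 (25.3%). WRKY8, which stood apart in the overlap of its strongest peaks, also had the lowest distal share of the WRKY lists, 31.9% (28.9% to 35.0%). With regions of 5 or more families left out, the WRKY and remaining means were 58.2% and 38.0%. With 5000 peaks the gap was smaller, 42.9% (n = 11) against 32.5%. Over the 89 lists the distal share was not related to list length (r = 0.154, rho = 0.0525, permutation p = 0.15 and 0.625; r = 0.155 without the 2 farthest).

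**Figure D4:**
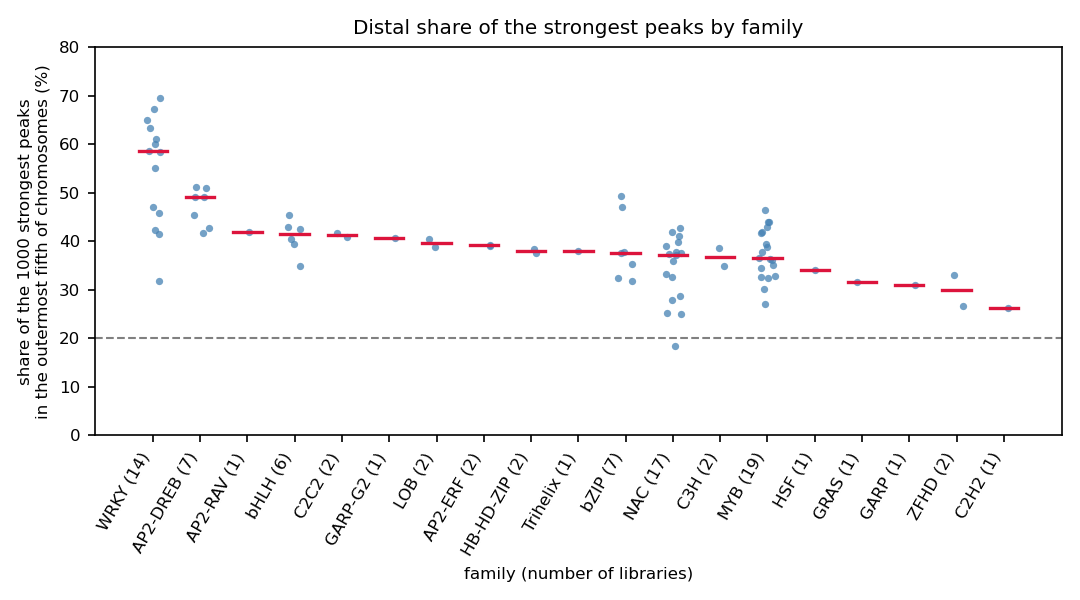
Share of the 1000 strongest peaks that lie in the outermost 20% of the chromosomes (percent, vertical axis) by family (horizontal axis, number of libraries in brackets). Each point is 1 library, each bar a family median, and the dashed line the 20% of evenly spread peaks; the WRKY lists run from 31.9% (WRKY8) to 69.5% (WRKY20).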

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

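The tests in this part were chosen after the results were seen, except the correlation of fold between libraries and the share of its variance by family, whose expected values were written down before.

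Over 5 measures, 16 sets of values of families with 4 to 10 libraries were examined, and in 2 of them, both of peak number, 1 library lay far from the others. Peak numbers are skewed, so the usual chance of 1 in 20 does not apply. bHLH10 had 159983 peaks, while the next of the 9 bHLH lists had 6746, and it also stood apart on the log10 scale (gap 0.556 of the range, limit 0.493). AP2-DREB-19, whose header names AP2-DREB-1, had 221871 peaks, against 81653 in the next of the 7 AP2-DREB lists; it did not stand apart on the log10 scale (0.268, limit 0.568), and it was the deepest of them (29.4 M fragments). The 27 lists with under 1000 peaks, which entered no overlap test with 1000 or more peaks, held 7217 of their 18763 peaks outside the regions of 5 or more families.

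Regions held by 5 or more families are a candidate for background DNA that the single expected value per library left in. Over the regions that both lists held (a median of 134 of the 1195) the fold enrichment of 2 libraries of different families followed a common profile, with a median Spearman correlation of 0.601 across regions (3213 pairs with at least 30 such regions, 98.6% of them positive; regions are not independent replicates), and the share of such peaks fell with list length (rho -0.749). Both are what an uneven background common to all libraries would give. Binding of many families to shared targets stays open: family explained 36.4% of the variance of log2 fold at the median of the 608 regions in at least 20 lists, where shuffled labels gave 30.2% in the median and up to 37.8% in 100 shuffles, which is within the range of the shuffles. Shuffled labels alone exceed the 25% set against the explanation, so this test could not have spoken against it and decides nothing. The Halo samples' own coverage, which would bear on this directly, was not analysed here.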

How the results depend on the processing

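The alternatives with depth, input folder, regions of 5 or more families, assembled chromosomes and the distal share were chosen after the data were seen, as were all those of the link between AP2-DREB and AP2-ERF and of the correlations. The family share of peak number kept its side of the threshold under all alternatives (22.7% to 32.0%, and 29.5% to 33.4% with each of the 17 libraries of families of 3 to 5 left out; no library of a larger family was left out), as did the distal share (51.8% to 65.8%). The same-family excess in overlap ran from 5.21 to 23.9 points with 500 or more peaks and from 7.28 to 7.84 points with each of the 12 libraries of families with 2 lists left out, none of them WRKY or AP2-DREB; with the 100 strongest peaks it was 3.15 points and no longer passed (permutation p = 0.181), and the cause was not tested. Ranking by fold changed no value, by construction.

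Of the families tested one by one, 2 passed in the main setting, 5 with 5000 peaks, 5 without regions of 5 or more families, 6 without regions of 10 or more libraries, 1 with 100 peaks and 1 without the libraries whose header names another member. These were not always the same families. With 100 peaks C2C2 alone passed, while WRKY shared 34.9% within and 30.2% outside (permutation p = 0.323, adjusted p = 0.523). AP2-DREB showed no excess there (permutation p = 0.99). With 500 peaks WRKY and C2C2 passed and AP2-DREB did not (permutation p = 0.116, adjusted p = 0.213). Leaving out regions shared by many families lowers the overlap between families by construction. Recurrent regions numbered 166 with 100 peaks, 2374 for at least 5 and 608 for at least 20 libraries, and 857 to 1406 under the others, above all shifts each time. The AP2-DREB with AP2-ERF overlap was 11.1% to 12.7% without either AP2-ERF library (permutation p = 0.0238 each, not adjusted over the 36 pairs), 10.3% without regions of 5 or more families and 9.52% with 1000 peaks, where it did not pass (permutation p = 0.934; cause not tested). Within the smaller input folder, list length with the share in many-family regions gave rho -0.370 (permutation p = 0.294) and fragments with peaks rho 0.507 (p = 0.056), with fewer libraries. No paired analysis was possible because replicate numbers only name different factors. Planned tests of motifs, promoters, repeats and gene groups, and their alternatives, were not run.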

Other observations

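All tests in this part were chosen after the data were seen. For 3 of them the expected values were written down before the values were computed. These were the areas under a curve for WRKY20 sites in MYB14 and for AP2-RAV-26 sites in MYB31, and the odds ratio.

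Lists differed in how many of their strongest peaks no other list held among its own strongest. Among the 5000 strongest peaks, HSF1 had 93.1% in no other list, NAC1 88.4%, and MYB19 and C2H2-4 85.1% each, while WRKY12 had 4.68%, WRKY15 7.10% and WRKY21 7.22%. The mean was 17.7% ± 18.8 (SD) over the 11 WRKY lists, 25.2% ± 11.4 over the 7 AP2-DREB lists and 56.6% ± 25.9 over the 8 NAC lists, and WRKY8 had 68.4%; these means depend on how many members of a family were assayed and were not tested. Peaks shared within 1 family only were stronger than peaks in no other list, while peaks shared across families were not compared. Lists with at least 50 peaks shared within the family only were used. In 41 of these 42 lists the median fold of such peaks was above that of peaks in no other list, with a median ratio of 1.22 (exact sign test over lists, two-sided, p = 1.96e-11). Lists of a family share peaks, so this p is too small. The ratio was highest in WRKY20 (2.19) and below 1 in NAC18 alone (0.967).

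Some short lists held many of the best sites of a relative. Of the 100 strongest WRKY13 sites outside regions of 5 or more families, 85 were in the list of WRKY30, which has 3336 peaks, and of those of WRKY8, 72 were in that of WRKY18 (3505 peaks). Of the 100 strongest NAC12 sites, 79 were in the list of NAC9 (1740 peaks) and 72 in that of NAC13 (1638 peaks). These pairs were picked. Over the 5000 strongest NAC12 sites outside regions of 5 or more families, site strength separated sites that NAC9 and NAC13 listed with areas under the curve of 0.791 and 0.839. No limit was set for these beforehand, and carry-over of DNA between these libraries was not decided. Over the other lists of a factor's family with at least 1000 peaks, the median recovery was 62% to 99% for the 14 WRKY factors and 52.5% to 90.5% for the 7 AP2-DREB factors, but 0% to 10% for MYB, 1% to 24% for NAC, 3% to 14% for bHLH and 4% to 14.5% for bZIP. In families with 2 such lists it was 91% and 97% for ZFHD, 99% and 100% for AP2-ERF, 45% and 48% for HB-HD-ZIP, and at most 12% for C2C2, C3H and LOB. These full lists differ in length, which was not taken into account. At least 5000 peaks were listed in 11 of 14 WRKY, 7 of 7 AP2-DREB and 5 of 7 bZIP lists. The counts were 6 of 19 in MYB, 8 of 17 in NAC and 2 of 6 in bHLH. The family list with the highest recovery held 11% to 100% of a factor's sites in MYB and 19% to 100% in NAC. In bHLH it held 14% to 99% and in bZIP 12% to 98%. Of the short WRKY lists, WRKY30 held 69.4% ± 16.7 (SD, n = 13), WRKY18 44.5% ± 11.8 and WRKY14 37.6% ± 23.9 of the other WRKY factors' sites. Some sharing crossed families: of the 100 strongest NAC1 sites, 48 were in the list of MYB12 (1495 peaks from the deepest library), and of those of MYB12, 70 were in the list of NAC1. For NAC1 sites in MYB12 the area under the curve was 0.769, and carry-over was not decided there either. ZFHD2, the longest list, held 74 of the 100 strongest MYB26 sites, and on average 57.9% ± 22.2 (SD) of those of the 14 WRKY factors, against 55.6% ± 29.0 in MYB14.

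MYB14 held 95 of the 100 strongest WRKY20 sites (exact 95% interval 88.7% to 98.4%) and 90 of those of WRKY21, while MYB13 held 68 and 64 and ZFHD2 85 and 76; among the 5000 strongest peaks WRKY20 overlapped MYB14 by 16.0%, ZFHD2 by 3.48% and MYB13 by 2.12%. A library of a WRKY factor alone under a wrong label is argued against, since MYB14 overlapped MYB26 by 13.9%, where the highest WRKY list reached 4.58%, although its mean overlap with the 11 WRKY lists (12.6%) was above that with its own family (7.82%) and above the lowest mean of a WRKY list with its family (11.7%). Carry-over of DNA from a WRKY library may explain the sharing and was not decided: the strength of a site in WRKY20 separated sites that MYB14 listed from those it lacked with an area under the curve of 0.794, between the 0.9 set for carry-over and the 0.75 set against it, and in WRKY21, for which no limit was set beforehand, with 0.722. A binding preference common to MYB14 and WRKY factors stays open as well, without a sequence to test it on.

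AP2-RAV-26 also shared sites with MYB lists: MYB13 held 96 and MYB31, with 3649 peaks, 77 of its 100 strongest sites. Carry-over between AP2-RAV-26 and MYB31 stays a candidate explanation, as site strength in AP2-RAV-26 separated sites that MYB31 listed with an area under the curve of 0.909. Of 294 same-family pairs 2 reached 0.9 (median 0.627), but these pairs mix long and short lists. MYB31 listed only 138 of the 5000 sites (2.76%). Other sites in short lists gave 0.847 (MYB13 in MYB31), 0.839 (NAC12 in NAC13), 0.791 (NAC12 in NAC9) and 0.769 (NAC1 in MYB12). Lists of like length were not tested as a set, so how far 0.909 is particular to this pair was not settled. A site type common to AP2-RAV-26, MYB13 and MYB31 stays a candidate too: of the 100 strongest MYB13 sites, AP2-RAV-26 and MYB31 both held 51 and both lacked 28, an odds ratio of 12.2 (Fisher's exact test, p = 4.06e-08). Sites of 1 library are not independent replicates, so this p is too small. Over 5000 MYB13 sites, strength separated those listed by MYB31 (0.847) and by AP2-RAV-26 (0.675). Site strength can thus raise the ratio without a common site type. The tests do not separate the explanations.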
